A study of Malus domestica with 6 samples.

How the data were processed

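RNA-seq libraries from the peel of 6 apples were analysed, 3 treated with EGCG and 3 controls. Groups and replicate numbers were taken from the sample titles. Controls are titled WT, and the design text describes them as treated in the same way with water. The treatment label of the control samples reads ddH2O2 where the design text has ddH2O. The control is called water here after the design text, and if the label were right every difference would be against another liquid. The design text states that 3 apples of each treatment were sequenced, so a library is taken as 1 apple. Per the labels' protocols, total RNA was extracted on columns and libraries were made with a VAHTS Universal V6 kit. No statement on strand was found in these labels, so reads of overlapping, antisense or near-identical genes may have been split between them.

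Values of 2 kinds, each in 1 table for all 6 libraries, were used. The first holds raw counts per gene identifier, as the authors deposited them. The submitters' processing notes name fastp, HISAT2, HTSeq, R 3.2.0 and DESeq2, with no role or order. The genome build and annotation are not given in the sources used here, so no coordinates are reported. The second table holds FPKM, as deposited by the authors. Counts and FPKM were checked against each other: dividing each count by its column total and its FPKM gave the same length for a gene in every library, to within 9.66e-08 of its value. That length was a whole number, within 0.01 bases, for 100% of the 34458 genes with any count. The FPKM values are thus the counts divided by the column total and by 1 length per gene (median 1439 bases), with no further scaling between libraries, and both tables describe the same reads. The other 12100 listed genes had no count in any library.

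None of the 46558 identifiers matched any of the 51804 genes of the reference table (RefSeq genes of apple assembly GDT2T_hap1) by gene number, locus tag, symbol, synonym or accession, and the deposited tables give no names. Before the data were examined, 30 lists of genes had been fixed as patterns on gene descriptions. They covered pathways, transcription factor families and markers of other cell types. With 0 identifiers matched, 0 members of any list could be found, so list tests were not run and cell types other than the peel were not checked. The rule for named genes, fixed at the same time, allowed at most 2 identifiers in each direction where descriptions are lacking. The 4 identifiers printed are the higher gene and the 2 lower genes with the smallest p, and the 1 gene called in the blocked fit. They were chosen after their values were seen.

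The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest with default settings, in R 4.3.3) on the counts, with TMM normalization, filterByExpr defaults, all 6 libraries, group as the only term and the contrast EGCG minus control. All p-values are two-sided unless stated otherwise, and adjusted p-values follow Benjamini and Hochberg over all tested genes, with 0.05 as the threshold. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM values use TMM-scaled library sizes, and log2 CPM for correlations and principal components used a prior count of 2. For genes read in one group only, raw counts were used, with 3 counts over the 3 libraries as the limit that a count of 0 allows. Such limits cover counting error only, because reads without molecular identifiers are not independent molecules.

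Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE and upper-quartile scaling, no filter and a stricter filter (at least 1 CPM in at least 3 libraries), a minimum absolute log2 fold change of 1, a test against a fold of 1.2, leaving out each library, the replicate number as a block, and limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5 or with no filter. The FPKM fits are on the log2(FPKM + pseudocount) scale, which understates changes of low genes. Added later were edgeR's newer quasi-likelihood method, DESeq2's unadjusted p combined with a 2-fold change, and the counts of genes read in one group only, also with libraries thinned to one total.

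The fits were tested on simulated data: negative binomial counts for the 24960 tested genes, drawn from the observed means, dispersions and library sizes of this comparison, with 200 genes changed in each of 5 runs. EdgeR recovered 83.6% of the genes changed 4-fold, 44.2% of those changed 2-fold and 5.37% of those changed 1.5-fold. DESeq2 recovered 89.1%, 62.7% and 20%. In the same runs edgeR also called at most 16 unchanged genes in a run, and DESeq2 at most 63. With no gene changed, edgeR called at most 3 genes in a run and DESeq2 at most 32. Each gene was drawn independently, so variation that genes share between libraries was not simulated. The biological coefficient of variation of the real libraries was 19.7%.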

Results

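Gene expression was measured by RNA-seq in the peel of Fuji apples. The apples had been held under vacuum for 5 min in either a 5 µmol per litre solution of epigallocatechin-3-gallate (EGCG, the main catechin of green tea) or water, and were then stored for 10 days. Water is the control liquid of the design text, while the control samples' treatment label reads ddH2O2, and which of them is right could not be settled here. Each treatment used 30 apples, of which 3 were sequenced, and each library is taken as 1 apple, so the comparison rests on 3 EGCG and 3 control libraries. According to the labels, the study addressed how EGCG changes skin greasiness and the keeping quality of stored fruit. The total counts were 18724866, 19030716 and 19549798 in EGCG replicates 1, 2 and 3. They were 19006915, 18204074 and 17564402 in control replicates 1, 2 and 3. Between 30362 and 30982 of the 46558 listed genes had at least 1 count in a library. The most abundant gene took between 5.42% and 7.83% of the counts of a library, and the 10 most abundant genes of each library took between 15.9% and 18.3%. The count and FPKM tables identify genes by identifiers that begin with MD and do not pair them with gene names. Results are therefore given by identifier and for groups of genes defined by their level, length or pattern of detection.

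All 3 EGCG libraries lay lower than all 3 control libraries on the main axis of variation, but EGCG replicate 3 and control replicate 2 lay close together on it. This axis, the first principal component of log2 CPM, held 40.04% of the variance. On it, EGCG replicates 1 and 2 lay at -41.5 and -58.7, and EGCG replicate 3 lay at 9.18. The controls lay at 33.2, 11.2 and 46.6. The difference of 60.7 between the group means was the largest of the 10 ways to split the 6 libraries 3 against 3 (exact permutation test, two-sided p = 0.1, the smallest p that 3 against 3 allows). The second component, with 20.03% of the variance, set control replicate 2 at 57.5 apart from the other 5 libraries, which lay between -20.7 and 4.36.

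**Figure D1:**
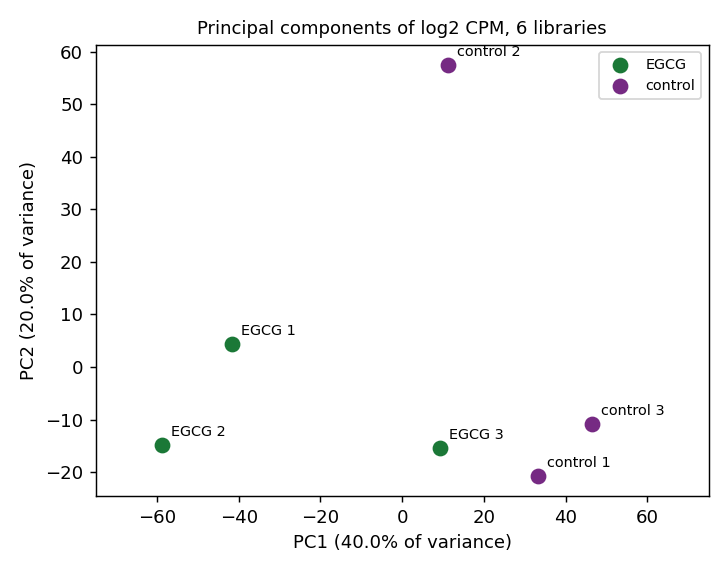
Each point is 1 library, placed by its first (horizontal) and second (vertical) principal component of log2 CPM, with the share of variance on each axis and the groups in colour. EGCG replicate 3, at 9.18 on the first component and -15.5 on the second, lies nearest to control replicate 1, and control replicate 2, at 57.5 on the second, lies apart.

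Correlations between libraries gave a similar picture. Pearson's r of log2 CPM across the tested genes averaged 0.970 over the 3 pairs of EGCG libraries, 0.971 over the 3 pairs of control libraries and 0.963 over the 9 pairs between groups. Genes are not independent replicates, so these values describe the libraries only. The mean r within groups exceeded that between groups by 0.00742, which 2 of the 10 splits matched or exceeded (exact permutation test, one-sided p = 0.2). EGCG replicate 3 had a mean r of 0.976 with the controls and 0.970 with the other EGCG libraries. EGCG replicates 1 and 2, in contrast, had mean r values of 0.959 and 0.954 with the controls and of 0.972 and 0.969 with the other libraries of their own group. The 200 genes with the smallest p between EGCG replicates 1 and 2 and control replicates 1 and 3 were used to place the other libraries. EGCG replicate 3 lay nearer to the EGCG side than control replicate 2 in a share of 0.315 of these genes. With control replicate 1 or control replicate 3 left out and placed instead, the share was 0.75 or 0.73. No pair of libraries was a duplicate: the chi-square of their counts exceeded its degrees of freedom at least 9.81 times in every pair.

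Of the 24960 genes with enough counts to test, none differed between EGCG and control peel at an adjusted p under 0.05 in edgeR's quasi-likelihood test. The smallest adjusted p was 0.117. At an unadjusted p under 0.05, 1081 genes were higher and 1092 were lower after EGCG. Together they made up 8.71% of the tested genes, against the 1248 genes expected with no effect. Limma-voom also called 0 genes, with 2145 at an unadjusted p under 0.05. DESeq2's Wald test with Benjamini-Hochberg adjustment called 263 genes, 152 higher and 111 lower after EGCG. All 239 of these that were also tested in edgeR had the same direction there and an unadjusted p under 0.05. Both tools fit the same counts, so this is no independent support for the calls. The median absolute log2 fold change of the DESeq2 calls was 1.25. The 263 calls came from a fit of all 46558 listed genes, while the simulation covered only the 24960 genes tested in edgeR. On simulated counts with no gene changed, DESeq2 called at most 32 genes in a run and edgeR at most 3. Each gene was drawn independently there, without variation that genes share between libraries, so false calls in the real libraries may be more frequent. Among the other splits of the 6 libraries, the one that sets EGCG replicates 1 and 2 and control replicate 2 against the rest gave 461 calls in DESeq2 and 53 in edgeR. The count of edgeR calls was sensitive to single libraries. Without EGCG replicate 3 it was 20, with 15 genes higher and 5 lower, and without control replicate 1 it was 16, with 2 higher and 14 lower. These calls had 0 genes in common.

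**Figure D2:**
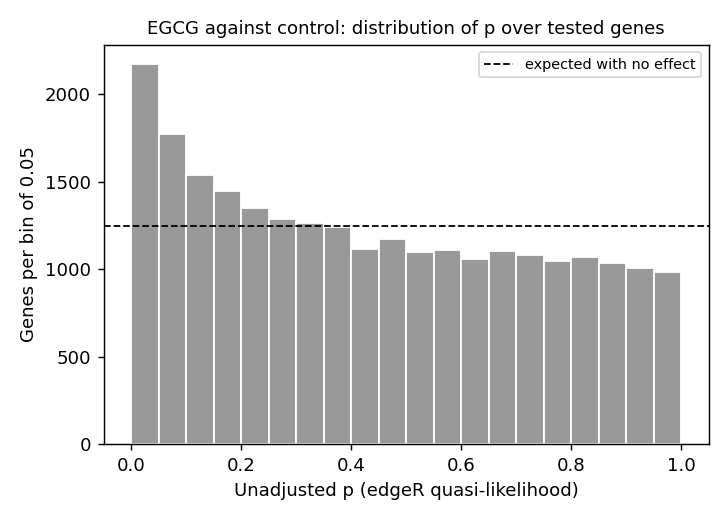
Bars give the number of tested genes (vertical axis) in each bin of 0.05 of the unadjusted edgeR p (horizontal axis), and the dashed line marks the number per bin expected with no effect. The lowest bin holds 2173 genes, above the line at 1248, and the highest bin holds 985.

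Genes with small p-values went in both directions at every expression level. Among the 6240 tested genes of lowest mean expression (0.368 to 3.14 CPM), 238 were higher and 214 lower at an unadjusted p under 0.05. In the next sets of 6240 genes by rising expression, 289 were higher and 305 lower, then 278 higher and 294 lower, and 276 higher and 279 lower in the highest set. By gene length, 288 were higher and 231 lower among the shortest 6248 genes. In the next sets by rising length, 258 were higher and 294 lower, then 290 higher and 283 lower, and 245 higher and 284 lower in the longest set. The median log2 fold change over all tested genes was -0.0017. The precision of single genes followed their level: the median standard error of a log2 fold change was 0.39 in the set of lowest expression and 0.11 in that of highest. Group values did not overlap in 1864 genes that were higher and 1748 that were lower after EGCG. This was 14.5% of the tested genes, where the average over all splits 3 against 3 is 10%. The share in each other split was not counted, so the difference cannot be assigned to EGCG. Among genes with a mean of at least 1 CPM, 312 were at least 2-fold higher and 367 at least 2-fold lower in the fitted values. Group values did not overlap in 174 and 136 of these.

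The genes with the smallest p in each direction differed between 3.73-fold and 4.47-fold. Among genes lower after EGCG, these were MD01G1208700 and MD00G1036100. MD01G1208700 stood at 6.86 ± 0.838 CPM (SD, n = 3) after EGCG and 28.8 ± 7.29 CPM (SD, n = 3) in controls. Its log2 fold change was -2.07 with a standard error of 0.20, 4.19-fold lower, and its edgeR adjusted p was 0.117. MD00G1036100 stood at 20.7 ± 7.96 CPM (SD, n = 3) after EGCG and 92.8 ± 2.21 CPM (SD, n = 3) in controls, 4.47-fold lower, with a log2 fold change of -2.16, a standard error of 0.23 and an edgeR adjusted p of 0.117. Its counts were 293, 304 and 593 in the EGCG libraries, so that EGCG replicate 3 lay nearest to the controls. Among genes higher after EGCG, MD01G1041900 had the smallest p. It stood at 5.71 ± 0.435 CPM (SD, n = 3) after EGCG and 1.53 ± 0.22 CPM (SD, n = 3) in controls, 3.73-fold higher, with a log2 fold change of 1.90, a standard error of 0.21 and an edgeR adjusted p of 0.117. All 3 EGCG values lay on one side of all 3 control values in each of these genes. None passed the threshold in edgeR with all libraries and the default filter, and DESeq2 called all 3, with adjusted p-values of 1.04e-15 for MD01G1208700, 2.04e-17 for MD00G1036100 and 1.52e-06 for MD01G1041900. In edgeR, MD01G1208700 passed without control replicate 1 (adjusted p 0.0210), MD00G1036100 passed without EGCG replicate 3 (adjusted p 0.00149), and both passed without a low-count filter (adjusted p 0.0250 each). Over 18 alternative settings the adjusted p of the 3 genes ran from these DESeq2 values up to 0.628. Their direction was the same in each, which the lack of overlap between the groups nearly fixed in advance.

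A further group of genes was read in one treatment only. In 115 genes every EGCG library had at least 1 count and every control library had 0, against 37 genes with the reverse pattern. With at least 3 counts in each library of the group, the numbers were 17 and 6. Among all 20 choices of 3 of the 6 libraries, the EGCG libraries gave the highest number at both minimums (1 of 20 choices, the smallest share that 3 of 6 libraries allow). The next highest, 97 and 12, both came from EGCG replicate 3 with control replicates 1 and 3. The split of these libraries against the rest is the one with 461 DESeq2 calls. Most of the 115 genes of the first set were close to the limit of detection, with a median of 8 counts summed over all libraries. Of the 115 genes, 6 had at least 20 counts in both EGCG replicates 1 and 2. They had between 77 and 3413 counts in EGCG replicate 1 and between 29 and 149 in EGCG replicate 2. In EGCG replicate 3 they had between 1 and 36 counts.

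The most abundant of them was MD10G1022900, with 3413, 128 and 36 counts in EGCG replicates 1, 2 and 3 and 0 in each control library. A count of 0 over the 3 controls allows up to 3 counts, or 0.0544 CPM, for counting error only. Against that limit its mean in the EGCG libraries was at least 1189-fold higher, and at least 80.0-fold higher without EGCG replicate 1, which held 95.4% of its EGCG counts. The spread between EGCG libraries was wide (64.7 ± 104.5 CPM, SD, n = 3), and edgeR's adjusted p was 0.460. With the replicate number as a block, it was the only gene called in edgeR, with an adjusted p of 0.0331. With 0 counts in every control, the block terms can take up the whole spread between the EGCG libraries. This blocked p therefore does not measure that spread, while the 0.460 of the fit without a block does. Over those of the 18 alternative settings that gave one, its adjusted p ran from 0.0331 to 0.791. DESeq2 gave it no adjusted p.

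**Figure D3:**
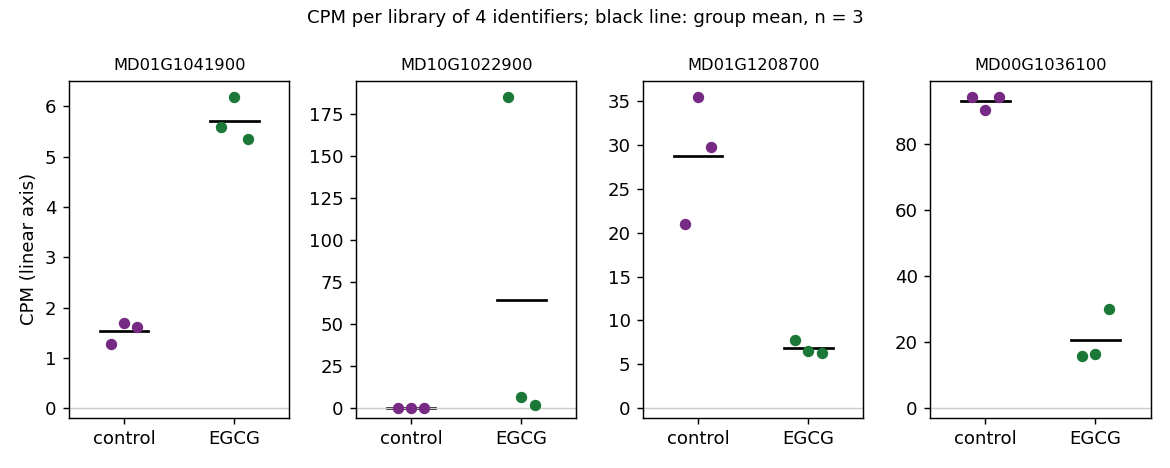
Each panel shows 1 gene identifier, with CPM on a linear vertical axis, control and EGCG libraries side by side, 1 point per library and a black line at the group mean. MD01G1208700 and MD00G1036100 were lower in all 3 EGCG libraries and MD01G1041900 was higher in all 3, while the EGCG mean of MD10G1022900, at 64.7 CPM, rests on 1 library.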

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

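The alternatives chosen only after the data were seen were edgeR's newer method, DESeq2's unadjusted p with a 2-fold minimum, and all counts of genes read in one group only. The count of genes called, 0 in edgeR, stayed at 0 with limma-voom, both other scalings, the stricter filter, the 2-fold minimum, the test against a fold of 1.2, all 3 FPKM fits and edgeR's newer method. DESeq2 called 263, and DESeq2's unadjusted p with a 2-fold minimum gave 802. Without a low-count filter 2 genes were called, MD01G1208700 and MD00G1036100, both lower. Leaving out 1 library gave between 0 and 20 calls, with 20 without EGCG replicate 3, 16 without control replicate 1 and 0 in the other 4 cases. MD00G1036100 was among the first and MD01G1208700 among the second. The cause of these differences was not tested. The number of genes at an unadjusted p under 0.05 stayed within 1.5 times its value of 2173 in all 17 alternatives. Of the 4 named genes, none changed direction in any of 18 alternatives each. This was nearly fixed in advance, since in each gene all 3 EGCG values lay on one side of all 3 control values. Genes read in every EGCG library and no control numbered 115, or 17 with a minimum of 3 counts, and the reverse set 37, or 6. Leaving out any 1 library gave between 180 and 246 and between 99 and 154, since fewer libraries have to meet the rule. The first set stayed the larger each time, but the 2 sets were closer in relative size than 115 and 37. They ran from 206 against 138 without control replicate 2 to 230 against 99 without EGCG replicate 2. With the replicate number as a block, 1 gene was called (MD10G1022900). Its 0 counts in every control let the block terms take up the spread between its EGCG counts, so this call does not measure that spread. The libraries are taken as sharing only a number, since the design text states separate apples. Deviations from the group means correlated at -0.16, 0.13 and 0.16 between same-numbered libraries. EGCG replicates 2 and 3 correlated best with the control of their own number. EGCG replicate 1 correlated best with control replicate 2 (0.14), and EGCG replicate 3 correlated at 0.14 with control replicate 1. With 3 libraries in a group such deviations are tied to each other, so these values leave pairing unsettled. Alternatives for gene lists were not run, because no identifier could be matched to a description. In the simulated counts edgeR recovered 5.37% of the genes changed 1.5-fold and 44.2% of those changed 2-fold. Any such gene may be missed, but 0 calls speak against as many changes as simulated if genes vary independently. In the real counts MD00G1036100, 4.47-fold lower, was not called in edgeR with all libraries and the default filter.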

Other observations

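The tests of neighbouring identifiers, of other splits, of a wrong label, of a swap, of a trend with gene length, of thinned libraries and of a foreign source were chosen only after the patterns were seen. The genes in the test of a foreign source were changed after a first result.

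Genes with small p-values tended to sit beside each other in the list of identifiers. Among the 2173 genes at an unadjusted p under 0.05, 172 pairs of neighbouring identifiers differed in the same direction, against a mean of 94.2 and a maximum of 122 in 1000 permutations (one-sided permutation p = 0.001, the smallest they can give), a ratio of 1.83. Pairs in opposite directions numbered 79, against 94.1 by chance. In the 9 other splits of the 6 libraries the ratio lay between 1.55 and 2.79, so it was not largest in the real split. Each of these splits still has more EGCG libraries on one side than on the other. None is thus free of a difference between the groups, and whether the excess is particular to EGCG cannot be told. Whether neighbouring genes vary together for a biological reason, or whether reads shared between similar neighbouring genes give the excess, was not tested, as sequences were not used here.

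The 6 libraries can be split 3 against 3 in 10 ways, which cannot give a share under 0.05. For genes at an unadjusted p under 0.05, the real split gave the highest count (2173, with 1978 as the highest other, 1 of 10 splits as large). EdgeR called 0 genes in the real split, which by itself makes all 10 splits as large, so this count decides nothing, and the highest other split called 53. At an adjusted p under 0.05, DESeq2 called 263 in the real split and 461 in the highest other, so that 2 of 10 splits were as large. In both tools the highest other split was the one that sets EGCG replicates 1 and 2 and control replicate 2 against the rest, while the remaining 8 splits gave 0 calls in edgeR and at most 15 in DESeq2. That split keeps EGCG replicates 1 and 2 against control replicates 1 and 3, as the groups do, so its calls may carry part of the group difference. Whether they reflect a structure of the libraries besides the groups was not tested. The split is the one that a swap of EGCG replicate 3 with control replicate 2 would make the real one.

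EGCG replicate 3 correlated better with the controls than with the other EGCG libraries, by 0.00651. A trend with gene length was not the whole cause, since removing it from each library left a gap of 0.00631. A swap with control replicate 2 stays open: among 200 genes chosen without both libraries, EGCG replicate 3 lay nearer to the EGCG side in a share of 0.315, as a swap needs. Control replicate 2 itself lay only midway, at a median position of 0.514 between the control mean at 0 and the EGCG mean at 1 (EGCG replicate 3 at 0.255). It had a higher mean r with the other controls (0.968) than with the EGCG libraries (0.965), of which EGCG replicate 3 had 0.972. Its r was 0.963 and 0.958 with EGCG replicates 1 and 2, against 0.969 and 0.967 with control replicates 1 and 3. A control apple labelled as EGCG replicate 3 also stays open, since the share was 0.75 against control replicate 1 and 0.73 against control replicate 3 when these were left out, but 0.315 against control replicate 2; carry-over of control RNA and a weaker response of that apple were not tested and stay open too.

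More genes were read in every EGCG library and no control (115) than the reverse (37). Deeper EGCG libraries do not account for this, since the first set was still 2.65 times the size of the second after all libraries were thinned to one total. One foreign RNA source in a fixed proportion per library would give all genes one ratio between the EGCG libraries, and over the 17 genes with at least 3 counts in each the ratios differed (chi-square of 48.5 per degree of freedom, or 11.5 without the most abundant gene, permutation p = 0.0001 for both, the smallest that 10000 resamples can give, counting error only). It stays open for part of the 115 genes. The 5 genes with at least 20 counts in EGCG replicates 1 and 2, the most abundant left out, did not differ detectably (1.68 per degree of freedom, permutation p = 0.0991). In 4 of them, counts in EGCG replicate 3 were 4.81% to 5.19% of those in EGCG replicate 1. They were 0.633% in the other, which is not among the 17, and 1.05% in the most abundant gene. Counts in EGCG replicate 2 ran more widely, from 21.5% to 43.3% of those in EGCG replicate 1 over the 5 genes, and were 3.75% in the most abundant gene. For counting chance in genes with few reads, 1 of the 20 choices of 3 libraries, the EGCG libraries themselves, gave as many as 17 genes. The highest other, EGCG replicate 3 with control replicates 1 and 3, gave 12. Since 20 choices cannot give a share under 0.05, genes switched on after EGCG are only a hypothesis.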
